A study of Homo sapiens with 18 samples.

How the data were processed

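Gene expression was measured by RNA sequencing of liver biopsies from infants, with 1 library per infant: 8 infants with biliary atresia, a blockage of the bile ducts outside the liver, and 10 with intrahepatic cholestasis, in which bile flow fails within the liver. The design text speaks of 19 infants, and 1 of the biliary atresia group is not analysed here. Per the labels' protocols, total RNA was isolated with a miRNeasy kit, libraries were made with the TruSeq Stranded mRNA kit, and sequencing was on an Illumina HiSeq instrument with single or paired ends. The labels do not say which library was sequenced in which way.

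Per the submitters' processing notes, the tools were TopHat2 2.1.0 and Cufflinks 2.2.1 and the genome build was GRCh37 (hg19). How these were set, and whether strand was used in counting, is not given in the sources used here. The deposited values are RPKM (reads scaled to transcript length and to the library's mapped reads), 1 per gene symbol, for 50181 rows that were the same in every library. No deposited value lay under 1, and 68.8% to 73.3% of the rows of a library held exactly 1, called the floor here, and 29514 rows (58.8%) stood there in all 18 libraries. 25 symbols were written as dates and could not be assigned to genes. 25 rows carried the accession of a mitochondrial genome with a running number, and these held 58.4% to 84.0% of the summed RPKM of a library. The sum of RPKM ranged from 2305200 to 6915700, so that it measures no depth. The number of reads behind a value is unknown, and no counting interval or detection limit was computed.

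The RPKM were analysed on the scale log2(RPKM + 1), on which a fold change understates the change of genes near the floor. Albumin (ALB) stood at the floor in 6 libraries, 3 in each group, while its lowest other value was 52129 RPKM. Such cells, at the floor in a row whose other values all exceeded 1000 RPKM, were taken as failed estimates and set to missing (12 cells in 6 rows). The filter chosen in advance, a value of at least 1 in at least 8 libraries, removes nothing from values floored at 1, and that plan had assumed FPKM where the deposited values are RPKM, which take the same test. It was replaced, after this was seen, by a value above the floor in at least 8 libraries, which 15129 rows met. After 31 sex-linked rows were left out, 15098 rows were tested, of which 11879 were protein-coding by the GENCODE 29 annotation. That annotation belongs to another build and was used only for gene types, names and transcript lengths, so no coordinates are given.

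The groups were compared with limma 3.58.1 in R 4.3.3 (linear model with a mean-variance trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). Fold changes are biliary atresia over intrahepatic cholestasis. Values for 15092 genes were simulated with normal noise drawn independently for each gene and library. On these the procedure recovered 68 of 100 genes changed by 1 log2 unit and 90 of 100 changed by 2, and 9 of its 167 calls were false. The simulated values hold no correlation between genes and no library that differs from the rest, so these rates need not hold for the real data.

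24 gene lists were tested: regulatory T cell, pan T cell, cytotoxic T and NK cell, type 2 and type 17 immunity, B and plasma cell, macrophage and Kupffer cell, neutrophil, inflammatory chemokine, cholangiocyte and ductular reaction, extracellular matrix and fibrosis, hepatic stellate cell, smooth muscle, sinusoidal endothelium, hepatocyte secreted protein, hepatocyte metabolism, bile acid synthesis, bile transport and its regulators, drug metabolism, fetal liver and growth, acute phase, interferon response, cell proliferation, erythroid, and tissue handling and early response. A library's list score was the mean log2(RPKM + 1) of the tested members. Scores were compared by a two-sided exact permutation test over all 43758 splits of 18 libraries into 8 and 10, adjusted over the 24 lists. Beside it stood limma's camera, with the correlation between genes preset at 0.01 or estimated, and fry. Members were also adjusted over the list alone. Relations of the regulatory T cell score to 6 other scores used Pearson's r and Spearman's rho with permutation p (exact for fewer than 10 libraries, 100000 resamples otherwise), in 18 relations. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

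Groups, tests, gene lists, the alternatives of pseudocount, filter, scaling, test and left-out libraries, and the rule for naming genes were fixed before the data were examined. The rule takes, among genes past the threshold with a mean of at least 2 RPKM in the higher group, the 10 with the largest fold in each direction, leaving out XIST, Y-linked genes, immunoglobulin and T cell receptor segments and symbols starting with LOC, LINC, MIR, SNORD or SNORA. It adds up to 4 members of each list with the smallest unadjusted p, and 19 genes of interest whatever their value: FOXP3, IL2RA, CTLA4, KRT7, KRT19, EPCAM, MMP7, COL1A1, COL3A1, ALB, CYP7A1, ABCB11, AFP, IL8, IL33, CD8A, CD3E, MKI67 and HBG2. 1 gene that the rule takes is not reported here. Alternatives added after the data were seen left out, or modelled, 4 libraries that stood apart, modelled the form of the sample code, took the 5 libraries with other forms alone, kept the failed estimates at the floor, or tested protein-coding rows only. Libraries were compared by their median Spearman correlation with the others over the tested rows, and those under 0.86, a limit set after the values were seen, were taken to stand apart.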

Results

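RNA sequencing of liver biopsies gave expression values for 8 infants with biliary atresia and 10 with intrahepatic cholestasis. The series concerns a molecular signature derived from regulatory T cells and its relation to outcome. The labels used here carry no outcome, so the comparison is between the 2 diseases. Each library stands for 1 infant, and 13423 to 15638 of 50181 rows lay above the floor of 1 RPKM in a library. Read depth is unknown for these values. 4 libraries stood apart from the other 14: biliary atresia replicate 6 and intrahepatic cholestasis replicates 5, 6 and 7. Their median Spearman correlation with the other libraries was 0.793 to 0.856, against 0.874 to 0.904 in the other 14. Their mean log2 level of mitochondrial mRNAs was 13.22 to 13.59, against 11.87 to 13.01. Sample codes came in a most common form (5 biliary atresia and 8 intrahepatic cholestasis libraries) and in others (5 libraries), and 476 genes differed between these forms by limma with the disease group in the model.

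The first question was which genes differ between the livers of the 2 diseases. Genes of bile duct epithelium and chemokines were among those that rose in biliary atresia. MMP7, a secreted protease made by epithelia, measured 79.4 ± 61.2 RPKM (SD, n = 8) in biliary atresia and 10.7 ± 11.0 (n = 10) in intrahepatic cholestasis, a fold of 8.86 on the log2(RPKM + 1) scale, which all folds here use. KRT19, a keratin of bile duct cells, measured 47.3 ± 28.2 against 8.43 ± 5.02 RPKM, a fold of 4.73. The tight junction protein CLDN4 (19.6 ± 13.1 against 3.29 ± 2.30 RPKM) was higher by 4.24 times. DEFB1, an antimicrobial beta-defensin, rose from 27.1 ± 23.4 to 112.1 ± 68.7 RPKM. CCL2, which attracts monocytes, and CXCL1, which attracts neutrophils, were higher by 3.69 and 3.44 times. The secreted protein WFDC2, the inhibitory ligand of T cells VTCN1 and the membrane protein PDZK1IP1 were higher by 3.05, 2.97 and 2.93 times.

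Other genes fell in biliary atresia. TIA1, an RNA-binding protein of stress granules, measured 27.8 ± 5.71 RPKM in biliary atresia and 54.1 ± 11.3 in intrahepatic cholestasis. The cyclophilin NKTR measured 10.3 ± 3.53 against 21.0 ± 4.13 RPKM. MAN2A2, a mannosidase of the Golgi (log2 fold change -0.84), TMX3, a thioredoxin of the endoplasmic reticulum (-0.90), and ANGEL1 (-0.79) fell too. POLE2, a subunit of a DNA polymerase, measured 1.27 ± 0.431 against 3.72 ± 1.53 RPKM and was above the floor in 4 of 8 biliary atresia libraries. The row RP11-27I1.2 fell by 1.20 on the log2 scale. HERC2P3 (-1.39), HERC2P2 (-1.25) and DDX11 (-1.15) have near-identical copies in the genome, so reads assigned to them are uncertain. The 5 other genes that fell, named after their values were seen, were ZNF37BP, GIGYF1, NFATC2IP, IARS and ZKSCAN4.

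**Figure D1:**
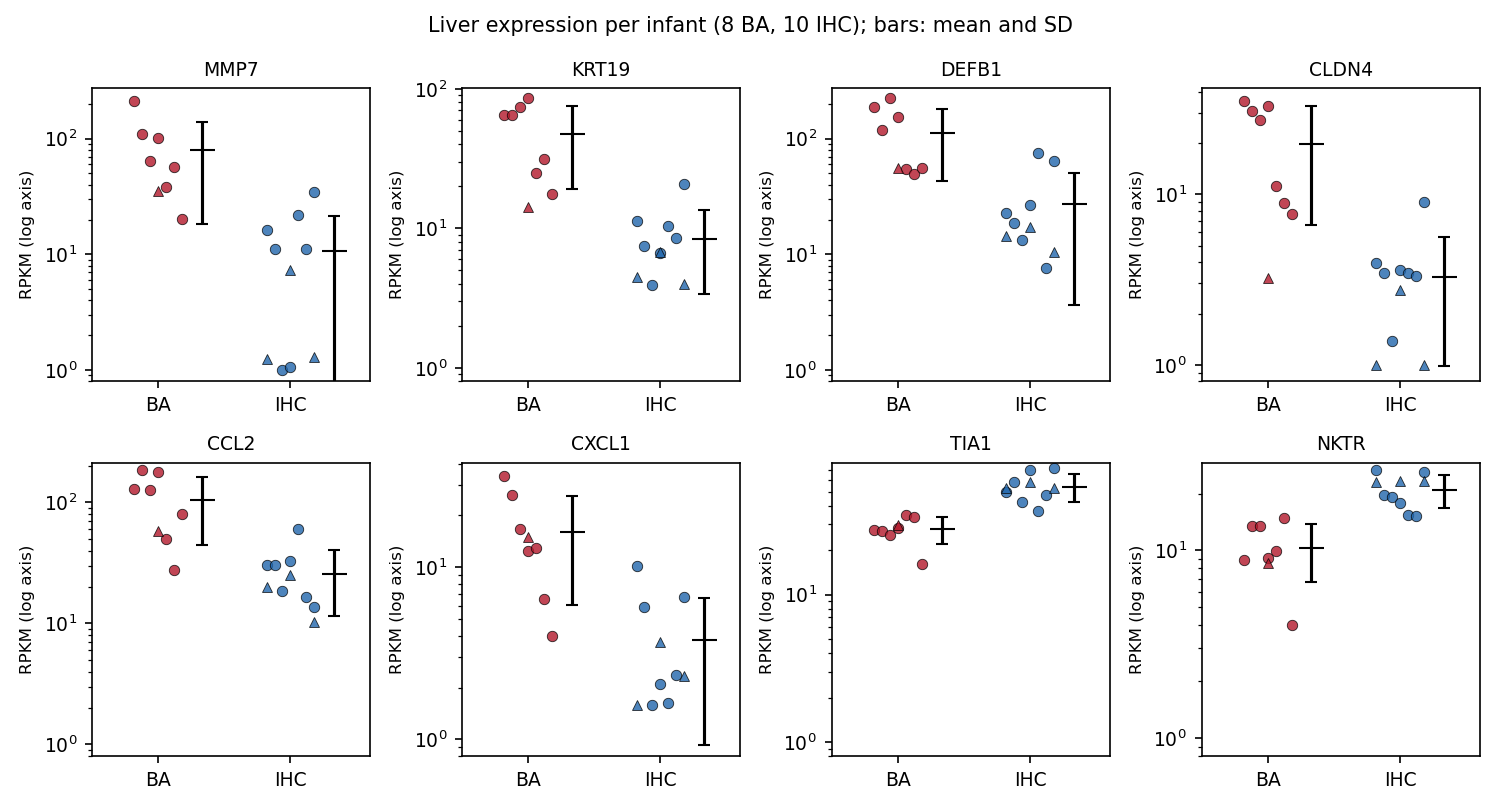
RPKM (log axis) of 8 of the genes that differed, for each infant with biliary atresia (BA, n = 8) and intrahepatic cholestasis (IHC, n = 10). Triangles are the 4 libraries that stood apart, horizontal marks are means and bars are SD, clipped at the lower edge of the axis where the mean minus the SD lies below it. MMP7, KRT19, DEFB1, CLDN4, CCL2 and CXCL1 have the higher mean in BA, and TIA1 and NKTR in IHC.

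In total 36 of 15098 genes passed the threshold in limma, 21 higher and 15 lower in biliary atresia, with adjusted p from 0.0231 to 0.0448. 1982 genes had an unadjusted p under 0.05. The median log2 fold change of all genes was 0.06, and 0.21 after scaling each library to the same sum. That scaling left 7 genes higher and 0 lower, upper quartile scaling gave 35 higher and 47 lower, and scaling to the same sum without the 50 highest genes gave 26 higher and 51 lower. The 36 genes kept their sign in each of the 38 limma fits that tested them, the main fit included. These fits reuse the libraries that picked the genes, so a kept sign is little support. The count rested on single libraries. No gene passed in limma without biliary atresia replicate 1, 3 or 4 or intrahepatic cholestasis replicate 3 or 6, where 1491, 1689, 1577, 1857 and 1640 genes had an unadjusted p under 0.05. The count was 19 without biliary atresia replicate 2 and 99 without replicate 6. It was 13, 6, 12, 9, 11, 65 and 114 without intrahepatic cholestasis replicate 1, 2, 4, 5, 7, 8 and 10. Without the 4 libraries that stood apart it was 9, of which 7 were among the 36. Within the most common form of sample code it was 99, of which 28 were among the 36, and with the code form in the model it was 59, which held all 36. In the 5 libraries with other codes, 3 with biliary atresia and 2 with intrahepatic cholestasis, limma gave 0 genes, and 849 had an unadjusted p under 0.05. An exact rank-sum test per gene gave 0 genes after adjustment and 1885 before it.

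Genes of cholangiocytes, the cells that line bile ducts, and of the ductular reaction were higher in biliary atresia as a group. The list score was 4.19 ± 0.58 (SD, n = 8) against 3.01 ± 0.56 (n = 10), a difference of 1.18 log2 units (exact permutation p = 0.00096, adjusted p = 0.0230). With an estimated correlation between genes, camera gave an adjusted p = 0.230. Of 23 members tested, 22 had a positive fold change. Over all genes 5 rose, among them MMP7, KRT19, CLDN4 and LAMB3, and 17 did when adjusted over the list alone. These included the keratin KRT7 (144.3 ± 88.01 against 39.99 ± 44.6 RPKM) and the adhesion protein EPCAM (45.6 ± 22.0 against 20.7 ± 18.1), which did not pass over all genes (limma adjusted p = 0.0904 and 0.198). The score was lower by 0.79 on average in the 4 libraries that stood apart than in the rest of their groups (-0.79). Without them the difference was 1.08 with an adjusted p = 0.0513. Within the most common code form it was 1.54 (adjusted p = 0.0373). In the 5 libraries with other codes it was 0.26 (exact permutation adjusted p = 0.933), where 3 against 2 libraries allow no p under 0.1. Among these, intrahepatic cholestasis replicate 10 scored 4.26, above the 3 of biliary atresia (3.48 to 4.02), and replicate 9 scored 2.88.

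Inflammatory chemokines were higher in biliary atresia as well. The score was 4.88 ± 0.65 against 3.80 ± 0.57, a difference of 1.08 log2 units (exact permutation p = 0.00242, adjusted p = 0.0230). The adjusted p was 0.230 with an estimated correlation in camera. All 14 tested members had a positive fold change, of which CCL2 and CXCL1 rose over all genes and 6 rose when adjusted over the list alone. Among the 6 were IL8, a chemokine of neutrophils, at 52.6 ± 33.8 against 12.01 ± 10.6 RPKM (limma adjusted p = 0.0524 over all genes), and CXCL6 at 26.6 ± 14.02 against 9.93 ± 11.1 RPKM. Genes that respond early to tissue handling, such as IER3 (72.1 ± 65.7 against 28.9 ± 27.8 RPKM) and DUSP1 (248.7 ± 111.3 against 146.1 ± 106.7), had a score difference of 0.84 with a positive fold change in 17 of 17 members, which did not pass (exact permutation adjusted p = 0.291), and 0 passed in limma over all genes or adjusted over the list alone, with 5 at an unadjusted p under 0.05. Without biliary atresia replicate 1 the adjusted p of the chemokine list was 0.0502, and without the 4 libraries that stood apart, in which the score differed by -0.63 from the rest of their groups, it was 0.0664. Within the most common code form it was 0.0435. In the 5 libraries with other codes the difference was 0.95 (exact permutation adjusted p = 0.800). Biliary atresia replicate 7 was the lowest of its group in both the handling and the chemokine score (3.87 and 3.80). Intrahepatic cholestasis replicate 1 was the highest of its group in both (6.59 and 4.85). The other extremes of the 2 scores fell in different libraries. Whether the chemokine difference goes with tissue handling was not tested.

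The subject of the series is regulatory T cells, and the list of genes chosen for them was higher in biliary atresia as a group. It rested on few measurable genes: 7 of 19 members were tested. Whether their score follows the number of these cells was not tested. The receptors IL2RA and CTLA4 were above the floor in 4 and 5 of 18 libraries and were not tested. Their means, near the floor, were not higher in biliary atresia. IL2RA measured 1.03 ± 0.06 against 1.18 ± 0.47 RPKM and CTLA4 1.12 ± 0.30 against 1.29 ± 0.46. The score was 2.69 ± 0.30 against 2.25 ± 0.21, higher in biliary atresia by 0.44 log2 units (exact permutation p = 0.00288, adjusted p = 0.0230). The adjusted p was 0.377 with an estimated correlation in camera. Of the 7 members, 6 had a positive fold change. No member passed in limma over all genes, and 5 had an unadjusted p under 0.05. Adjusted over the list alone, 4 were higher and 1 was lower. LAYN, a receptor for hyaluronan (1.93 ± 1.15 against 1.03 ± 0.0721 RPKM, above the floor in 7 of 8 and 2 of 10 libraries), BATF, a transcription factor (6.13 ± 2.30 against 3.20 ± 1.87), IL1R2, a decoy receptor for interleukin 1 (6.25 ± 3.85 against 3.15 ± 1.05), and LRRC32, which holds latent TGF-beta at the cell surface and was named after its value was seen, were higher. IKZF4, a transcription factor that acts with FOXP3, measured 1.20 ± 0.226 against 1.79 ± 0.420 RPKM. FOXP3, the transcription factor that defines these cells, measured 9.60 ± 3.22 against 6.82 ± 6.79 RPKM and did not pass (limma adjusted p = 0.405 over all genes, 0.0718 over the list). It lay above the T cell gene CD3E in 14 of 18 libraries, and it overlaps the neighbouring gene CCDC22 on the other strand, while the use of strand in counting is not given. Without biliary atresia replicate 1 the list's adjusted p was 0.0502, and without the 4 libraries that stood apart, in which the score differed by -0.25 from the rest of their groups, it was 0.0513. Within the most common code form it was 0.0435, and in the 5 libraries with other codes the difference was 0.17 (exact permutation adjusted p = 0.800). The list did not pass with no filter on low values (a difference of 0.20, adjusted p = 0.0872) or with a mean of at least 5 RPKM (0.51, adjusted p = 0.106).

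Genes of the extracellular matrix had a positive fold change in 31 of 31 members, with a score difference of 0.83 log2 units, but the list did not pass (5.76 ± 0.62 against 4.94 ± 0.74, exact permutation p = 0.0242, adjusted p = 0.145). With an estimated correlation in camera the adjusted p was 0.453. No member passed in limma over all genes, where 18 had an unadjusted p under 0.05, and 9 did when adjusted over the list alone. These included TIMP1, an inhibitor of matrix proteases (600.0 ± 213.6 against 310.8 ± 126.7 RPKM), the proteoglycan LUM (124.2 ± 81.3 against 41.6 ± 31.3), FAP and LOXL1. The collagens COL1A1 (405.0 ± 210.1 against 228.2 ± 147.4 RPKM) and COL3A1 (454.2 ± 204.0 against 234.0 ± 129.9) did not pass. The score of the 4 libraries that stood apart differed by -1.38 from the rest of their groups. The difference passed without biliary atresia replicate 6 (1.02, adjusted p = 0.0253) or with an indicator of the 4 libraries in the model (0.58, adjusted p = 0.0227). Within the most common code form it was 0.9995 (adjusted p = 0.201), and in the 5 libraries with other codes 0.09 (exact permutation adjusted p = 0.933).

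The remaining lists did not pass, by exact permutation adjusted over the 24 lists. For T cells and other immune cells the score differences were 0.33 for pan T cell genes (adjusted p = 0.291), 0.36 for cytotoxic T and NK cells (0.392), 0.12 for type 2 and type 17 immunity (0.612), 0.03 for B and plasma cells (0.943), 0.33 for macrophages and Kupffer cells (0.618) and 0.44 for neutrophils (0.461). Fold changes were positive in 11 of 12, 14 of 14, 6 of 8, 4 of 11, 17 of 17 and 10 of 13 of the tested members of these lists. For B and plasma cells the median member had a fold change of -0.09, and camera gave the negative direction. CD3E measured 5.92 ± 4.57 against 3.12 ± 2.23 RPKM, CD8A 4.70 ± 6.55 against 1.65 ± 1.66, IL33 11.3 ± 4.63 against 10.4 ± 6.37, and C1QA of macrophages 176.98 ± 96.95 against 129.4 ± 68.6. The difference was 0.32 for hepatic stellate cells (0.392), 0.17 for smooth muscle (0.392) and 0.09 for sinusoidal endothelium (0.805), with positive fold changes in 11 of 13, 4 of 7 and 10 of 15 members. Adjusted over the list alone, MYH11 (4.26 ± 1.94 against 2.12 ± 0.902 RPKM) and CNN1 (1.99 ± 0.965 against 1.10 ± 0.263) of smooth muscle and PLVAP of endothelium (15.1 ± 4.48 against 7.42 ± 3.89 RPKM) were higher. No member of any of these 9 lists passed in limma over all genes, 10 had an unadjusted p under 0.05, and those 3 were the only members that passed over their list. When each library was left out in turn, the 9 differences ranged from 0.19 to 0.40, 0.18 to 0.46, 0.05 to 0.20, -0.05 to 0.20, 0.15 to 0.58, 0.31 to 0.64, 0.22 to 0.42, 0.13 to 0.26 and 0.01 to 0.20 in the order given, and none passed. After scaling to the same sum those of type 2 and type 17 immunity, macrophages and endothelium were 0.26, 0.52 and 0.28.

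Genes of hepatocyte function did not differ in this test. The score differences were 0.24 for secreted proteins (adjusted p = 0.291), 0.13 for metabolism (0.612), 0.16 for bile acid synthesis (0.477), 0.01 for bile transport and its regulators (0.943) and 0.23 for drug metabolism (0.531). Fold changes were positive in 18 of 20, 13 of 20, 10 of 13, 10 of 17 and 13 of 18 members, and camera gave the negative direction for bile transport. The score differences were -0.10 for fetal liver and growth (0.805), -0.25 for acute phase (0.477) and -0.01 for interferon response (0.970), with negative fold changes in 9 of 14, 7 of 13 and 12 of 21 members. After scaling to the same sum the first 5 differences were 0.55, 0.43, 0.42, 0.24 and 0.54, and none passed. When each library was left out in turn, they ranged from 0.17 to 0.29, 0.06 to 0.20, 0.11 to 0.24, -0.02 to 0.06 and 0.16 to 0.41, and the last 3 from -0.22 to -0.01, -0.35 to -0.14 and -0.11 to 0.19. Scaling turned the sign of the last 3 and of B and plasma cells, endothelium, metabolism and bile transport in at least 1 setting. 0 members of these 8 lists passed in limma over all genes or adjusted over the list alone, and 12 had an unadjusted p under 0.05. ALB measured 70719 ± 13513 RPKM (n = 5) against 80485 ± 16073 (n = 7) where it was estimated. The bile salt export pump ABCB11 measured 15.7 ± 7.63 against 18.6 ± 9.32 RPKM, and AFP, a serum protein of fetal liver, 111.3 ± 224.9 against 298.2 ± 385.8. The fold changes of ALB and ABCB11 were -0.18 and -0.23, and 0.36 and 0.06 after scaling to the same sum. CYP7A1, the rate-limiting enzyme of bile acid synthesis, was above the floor in 2 of 8 and 1 of 10 libraries and was not tested. Cell proliferation genes had a score difference of -0.47 (adjusted p = 0.197) and erythroid genes one of -1.47 (0.291), with a negative fold change in 18 of 18 members of either list. After scaling to the same sum these were -0.19 and -1.04, and over left-out libraries they ranged from -0.56 to -0.35 and from -1.81 to -1.19. In the 5 libraries with other codes the proliferation difference was 0.15, with the other sign.

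**Figure D2:**
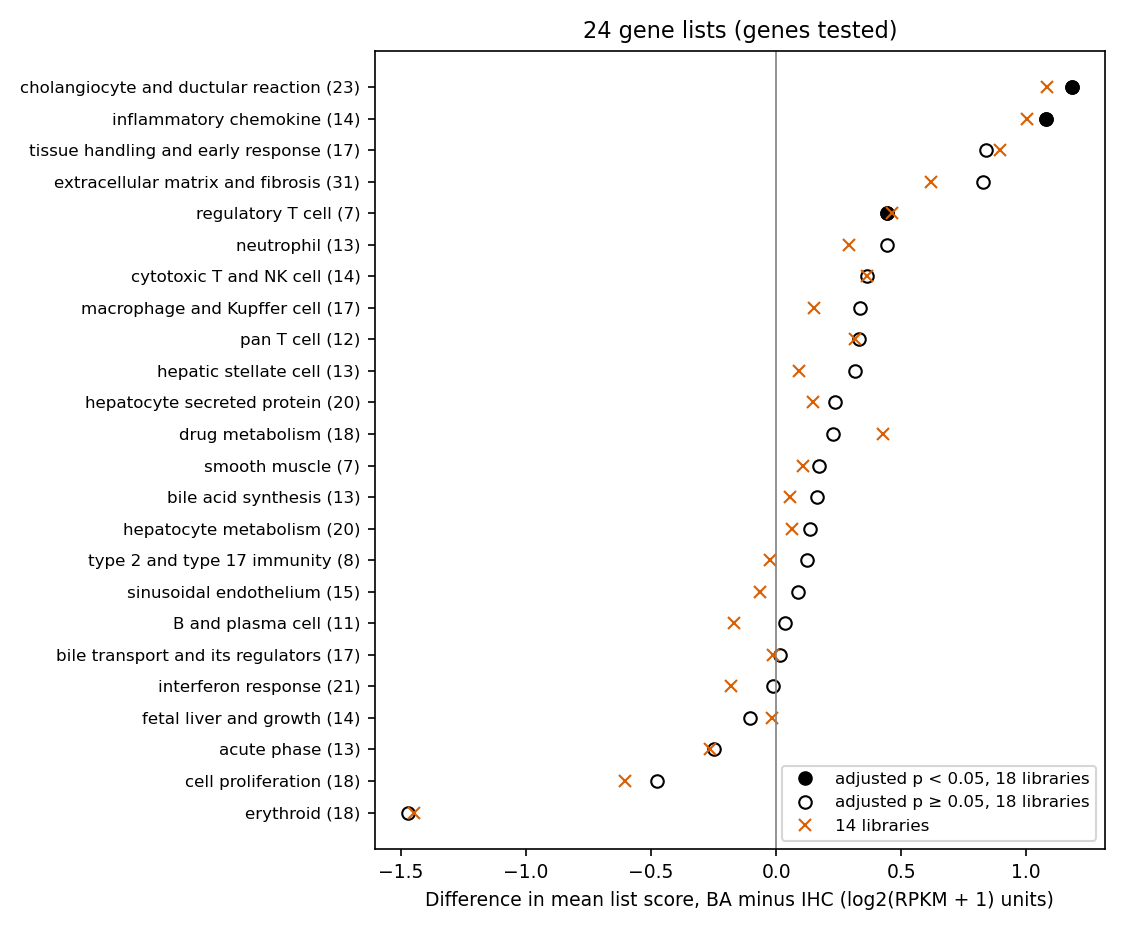
Difference in mean list score (log2 units, horizontal axis), biliary atresia (BA) minus intrahepatic cholestasis (IHC), for 24 gene lists with the number of genes tested in brackets. Circles are 18 libraries, filled where the adjusted p was under 0.05, and crosses are the 14 libraries without the 4 that stood apart. The cholangiocyte list differs by 1.18 and the erythroid list by -1.47.

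Whether the regulatory T cell score moved with other scores between infants was tested in 18 relations, of which 5 passed after adjustment by Pearson's r and 3 of these 5 by Spearman's rho too. 2 of the 3 pooled all libraries, with r = 0.88 for the cholangiocyte and 0.76 for the matrix score. In the 14 libraries that did not stand apart these were 0.87 and 0.75 (permutation adjusted p = 0.00324 and 0.0107). Pooled values also carry the differences between the 2 disease groups, so values within a group are given. In biliary atresia (n = 8) the score rose with the cholangiocyte score, with r = 0.93 (exact permutation p = 0.00179, adjusted p = 0.0107) and rho = 0.95 (exact permutation p = 0.00114, adjusted p = 0.00685). Without the 2 libraries farthest from the group median of the regulatory T cell score r was 0.86 (exact permutation p = 0.0569), and without the 2 farthest from the median of all 18, both of this group, it was 0.92 (exact permutation p = 0.0236, adjusted p = 0.106). In the 7 biliary atresia libraries that did not stand apart r was 0.89 (exact permutation p = 0.0103, adjusted p = 0.0619) and rho was 0.93 (exact permutation p = 0.00675, adjusted p = 0.0405), so that rho passed and r did not. In intrahepatic cholestasis (n = 10) r was 0.61 (permutation p = 0.0721, adjusted p = 0.176) and rho was 0.68 (permutation p = 0.0349, adjusted p = 0.0928). Without the 2 farthest libraries r was 0.44. In the 8 intrahepatic cholestasis libraries of the most common code form r was 0.79 (exact permutation p = 0.0187, adjusted p = 0.0746). The 5 of biliary atresia, under the minimum of 6 set for a correlation, were not tested. With quantile normalization r was 0.88 in biliary atresia (exact permutation adjusted p = 0.05045) and 0.09 in intrahepatic cholestasis.

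With the matrix score, r was 0.76 in biliary atresia (exact permutation p = 0.00987, adjusted p = 0.0444) and rho was 0.69 (exact permutation p = 0.0694, adjusted p = 0.139). Without the 2 libraries farthest from the group median r was 0.31 (exact permutation p = 0.603), and without the 2 farthest from the median of all 18 it was 0.68 (exact permutation p = 0.115, adjusted p = 0.259), so the relation passed in neither set of 6. In intrahepatic cholestasis r was 0.58 (permutation p = 0.0780, adjusted p = 0.176). With hepatocyte metabolism r was 0.73 in intrahepatic cholestasis (permutation p = 0.0136, adjusted p = 0.0488) and rho was 0.70 (permutation p = 0.0297, adjusted p = 0.0928), with r = 0.82 without the 2 farthest libraries. In the 7 intrahepatic cholestasis libraries that did not stand apart r was 0.66 (exact permutation p = 0.131), in the 8 of the most common code form 0.72 (exact permutation p = 0.0379, adjusted p = 0.114), and with quantile normalization 0.20 (permutation adjusted p = 0.758). For the matrix score in biliary atresia r was 0.54 in the 7 libraries that did not stand apart (exact permutation p = 0.198) and 0.42 with quantile normalization (exact permutation adjusted p = 0.731). With the pan T cell score r was 0.02 (exact permutation p = 0.952) and rho was -0.02 in biliary atresia, with r = -0.14 without the 2 libraries farthest from the group median. In intrahepatic cholestasis r was 0.38 (permutation p = 0.284), rho was 0.67 (permutation p = 0.0398, adjusted p = 0.0928) and r was 0.66 without the 2 farthest (exact permutation p = 0.0694), so these estimates differed in size and none passed after adjustment.

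**Figure D3:**
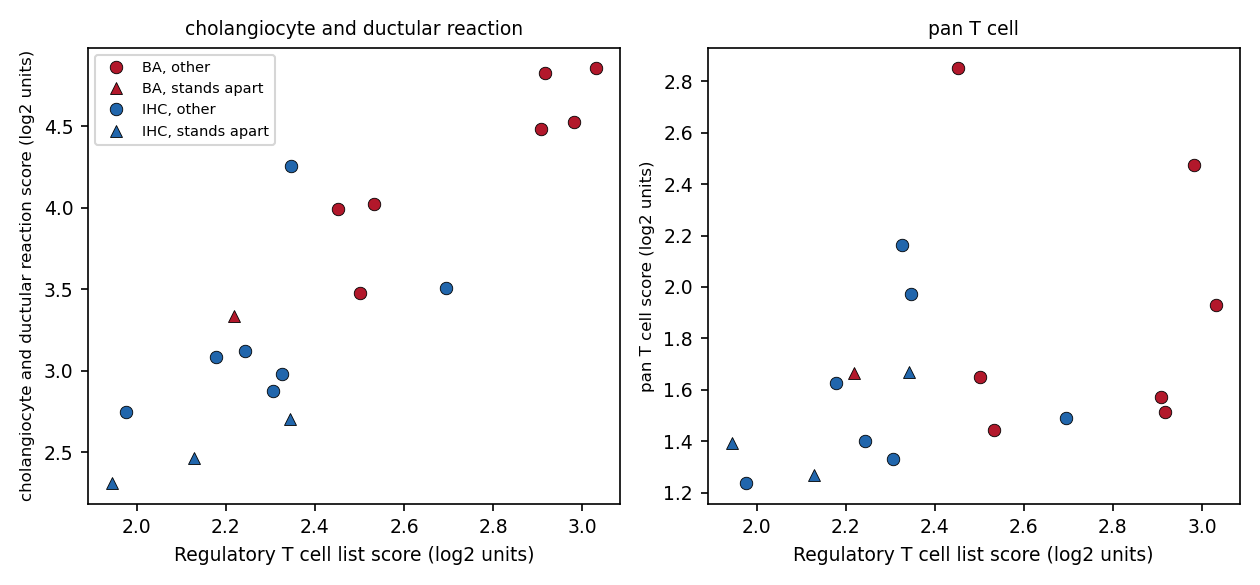
Regulatory T cell list score (horizontal axis, log2 units) against the cholangiocyte and the pan T cell list scores (vertical axes, log2 units), 1 point per infant with biliary atresia (BA, n = 8) or intrahepatic cholestasis (IHC, n = 10). Triangles are the 4 libraries that stood apart. Within BA r is 0.93 for the cholangiocyte score and 0.02 for the pan T cell score.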

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

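The tests of the disease group as the source of the 4 libraries that stood apart, of these libraries as the source of the cholangiocyte difference and of regulatory T cells as the source of FOXP3 were chosen after the results were seen, as were the 4 libraries themselves.

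10 values lay farther from the rest of their group than Dixon's limit allows, among 124 groups of values tested, where chance alone gives about 1 in 20. Biliary atresia replicate 6 was the lowest of its group in the type 2 and type 17 immunity score (2.90, next 3.34), the extracellular matrix score (4.42, next 5.59), the smooth muscle score (2.09, next 2.59), EPCAM (10.6 RPKM, next 32.9) and the median Spearman correlation with other libraries (0.8445, next 0.8832). Biliary atresia replicate 8 was the lowest in NKTR (3.98 RPKM, next 8.57) and TIA1 (16.0 RPKM, next 25.6). Intrahepatic cholestasis replicate 1 was the highest in the interferon response score (5.47, next 3.92) and CD8A (6.29 RPKM, next 2.08). Intrahepatic cholestasis replicate 10 was the highest in WFDC2 (7.97 RPKM, next 2.48).

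4 libraries stood apart from the other 14, with lower rank correlation, more mitochondrial mRNA and lower macrophage (-1.55), neutrophil (-1.22) and matrix (-1.38) scores than the rest of their groups. The disease group alone does not separate them, since 1 of 8 biliary atresia and 3 of 10 intrahepatic cholestasis libraries were among them. With so few libraries, whether they are more frequent in 1 group cannot be told. The 4 libraries follow one another directly in the order of deposit, and all 4 have the most common form of sample code. The labels name no batch, so a shared step of processing cannot be told apart from other causes. A biopsy with fewer cells other than hepatocytes would lower the scores of 5 other cell types alike, but their differences ranged over 1.371 log2 units, or 0.785 without the pan T cell list near the floor, and in each of the 4 the matrix score was lower by more (-1.10 to -1.55) than the endothelium score (-0.63 to -0.92). The hepatocyte secreted protein score was lower too (-0.48). So were metabolism (-0.48), bile acid synthesis (-0.57) and bile transport (-0.28), while drug metabolism was higher (0.21). These scores are unscaled. Trimmed mean scaling gave the 4 libraries factors of 0.757 to 0.875, against 0.933 to 1.145 in the other 14, so their values lay lower in general. The hepatocyte scores therefore cannot count for or against fewer other cells. Breakage of RNA was examined through transcript length. Folds against the rest of the group fell with length across 11877 genes in each of the 4, with a highest rho of -0.163. But 3 of the other 14 libraries had stronger trends than any of the 4 (-0.2273 to -0.3133). The libraries that the 4 were set against included those of other codes, with rho of -0.0426 to 0.378. The code form may thus enter the trend. Whether RNA breakage contributed remains open and cannot be told apart from other causes.

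Cholangiocyte genes were higher in biliary atresia by 1.18 log2 units. Without the 4 libraries that stood apart the difference was 91.7% as large (1.08, with scores of 4.31 ± 0.50, n = 7, against 3.23 ± 0.51, n = 7, where they had been 4.19 ± 0.58 and 3.01 ± 0.56), and its adjusted p moved from 0.0230 to 0.0513 with fewer samples, while with an indicator of the 4 libraries it passed (1.04, adjusted p = 0.0227). With an estimated correlation in camera it did not pass (adjusted p = 0.230), and in the 5 libraries with other codes, 3 against 2, the difference was 0.26. A lower share of hepatocytes that raises other cell types alike would raise the cholangiocyte, endothelium and macrophage scores equally. The cholangiocyte score rose by 0.97 more than the mean of the other 2 (exact permutation p = 0.02795, unadjusted). This argues only against a rise alike in these lists. The matrix score, which was not in this test, differed by 0.83 with 31 of 31 members positive. A biopsy make-up that raises some cell types and not others is therefore not excluded. More bile duct cells in biliary atresia, a change of expression within them and differences between infants that the labels do not give stay open and were not tested.

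FOXP3 was above 5 RPKM in 13 libraries, while IL2RA stood at the floor in 9 and CTLA4 in 8 of these, and both in 6. With regulatory T cells as the source of most of this signal, FOXP3 would stay below CD3E, which every T cell expresses. FOXP3 lay above CD3E in 14 of 18 libraries, by 0.73 log2 units on average (exact sign-flip permutation p = 0.00386). This expectation was written after the results were seen, so the p-value is no independent support. RPKM of 2 different genes need not be comparable as cell numbers. The values therefore argue against that source only if they are, and do not rule it out. Reads from CCDC22, a neighbouring gene that overlaps FOXP3 at its end, would make the 2 rise together, but rho was -0.139 over 18 libraries (permutation p = 0.580, adjusted p = 0.580 over 5 relations), and in the 14 that did not stand apart rho was -0.275 (permutation p = 0.340, adjusted p = 0.535) and r was -0.36 (permutation p = 0.206, adjusted p = 0.343, -0.67 without the 2 farthest libraries). With so few libraries this cannot be told apart from a weak relation, and whether strand was used in counting is not given in the sources used here. Expression of FOXP3 in other cells was not tested.

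The 36 genes of the group comparison were set against other splits of the 18 libraries into 8 and 10. Of 100 splits, only the real one (1 of 100) gave as many genes, and the highest of the others gave 5. For the 3 lists it was again 1 of 100 splits, and the highest of the others gave 2 lists. With 100 splits no share under 1 of 100 can be shown, and the splits took no account of the code form or of the 4 libraries. For the lists they repeat the permutation test that called them. The other splits drawn thus gave smaller counts, which does not show that any single gene or list differs.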

How the results depend on the processing

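The fits without the 4 libraries that stood apart, with an indicator of them, with the code form in the model, of the 5 libraries with other codes and of protein-coding genes alone were chosen after the data were seen. The count of 36 genes became 23 with no filter on low values (where more genes are tested), 7 after scaling to the same sum, 82 with upper quartile scaling, 58 with trimmed mean scaling, 83 with quantile normalization, 77 with scaling to a sum without the 50 highest genes, 367 with array weights and 0 with the exact rank-sum test (smallest adjusted p 0.0805). It became 99 within the most common code form, 59 with the code form in the model, 0 in the 5 libraries with other codes (fewer samples), 9 without the 4 libraries (fewer samples), 88 with an indicator of them, and 0 to 114 when each library was left out in turn. Except for the fits with fewer samples or more genes, the cause was not tested. It stayed within 1.5 times in the other 7 settings, such as other pseudocounts and protein-coding genes alone (41).

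The count of 3 lists was 0 without the 4 libraries, 0 in the 5 libraries with other codes, 10 with camera at the preset correlation, 0 with the estimated one, 3 with fry, and 1 to 4 when each library was left out in turn. The regulatory T cell difference of 0.44 lost its call with no filter (0.20), with a mean of at least 5 RPKM (0.51), without the 4 libraries (0.46), in the 5 with other codes (0.17) and with the estimated correlation (adjusted p = 0.377), and ranged from 0.40 to 0.51 over left-out libraries, being lost without biliary atresia replicate 1. The cholangiocyte difference of 1.18 lost its call without the 4 libraries (1.08), in the 5 with other codes (0.26) and with the estimated correlation (adjusted p = 0.230), and ranged from 1.09 to 1.32 over left-out libraries. The chemokine difference of 1.08 lost its call without the 4 libraries (1.002), in the 5 with other codes (0.95) and with the estimated correlation (adjusted p = 0.230), and ranged from 0.95 to 1.23 over left-out libraries, being lost without biliary atresia replicate 1. The matrix difference of 0.83 passed with an indicator of the 4 libraries (0.58) and with camera at the preset correlation (adjusted p = 1.24e-11), and ranged from 0.70 to 1.02 over left-out libraries, passing without biliary atresia replicate 6 (1.02). None of these 4 differences changed sign. Beyond the fewer samples, the cause was not tested.

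Of the 18 relations of the regulatory T cell score, 5 passed by Pearson's r and 3 by Spearman's rho. By r it was 3 with z-scored members, 1 with quantile normalization, 2 within the most common code form (of 12 relations), 2 without the 4 libraries and 2 without the 2 libraries farthest from the median of all 18. By rho these were 2, 1, 2, 3 and 2, and the cause was not tested. Genes named that did not pass turned in sign: the ALB log2 fold change to 0.000182 without the 4 libraries and to 0.36 after scaling to the same sum, the ABCB11 log2 fold change to 0.06 after that scaling, and the IL33 log2 fold change to -0.23 without them and to -0.00537 with an indicator of them. No paired analysis was possible because the replicate numbers were given in accession order and pair no infants. Since no read counts are known, the limits that depth sets on low values could not be computed, and levels under the floor of 1 RPKM are unknown.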

Other observations

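The comparison of sample codes with the disease group in the model was chosen after the result was seen.

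Genes of red blood cell formation had a negative fold change in biliary atresia in 18 of 18 members, without the list passing (score 3.52 ± 0.98, n = 8, against 4.99 ± 2.28, n = 10, exact permutation p = 0.109, adjusted p = 0.291, and 0.465 with an estimated correlation in camera). No member passed in limma over all genes, where 9 had an unadjusted p under 0.05, and 6 fell when adjusted over the list alone, among them KLF1, the master transcription factor of red cell formation (1.13 ± 0.234 against 8.73 ± 9.72 RPKM), EPB42 of the red cell membrane (1.54 ± 0.4997 against 13.6 ± 13.9) and the transport protein RHAG (1.11 ± 0.258 against 7.47 ± 8.36). The fetal globin HBG2 measured 215.5 ± 194.9 against 3537 ± 5892 RPKM. Genes of cell division had a negative fold change in 18 of 18 members (exact permutation p = 0.0410, adjusted p = 0.197, and 0.453 with an estimated correlation in camera). 2 of them fell when adjusted over the list alone, TOP2A (7.97 ± 2.11 against 16.96 ± 8.95 RPKM) and AURKB (4.08 ± 0.903 against 8.52 ± 3.86), and none in limma over all genes, where 6 had an unadjusted p under 0.05. MKI67 measured 2.76 ± 1.17 against 5.16 ± 3.13 RPKM. The score of intrahepatic cholestasis libraries that stood apart lay on both sides of their group, from -2.72 in replicate 7 to 2.03 in replicate 6 for erythroid genes.

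A candidate explanation is blood cell formation in the liver, which persists after birth to an extent that differs between infants and would raise both lists together within each group. The Pearson correlation of the 2 scores was 0.08 in biliary atresia (exact permutation p = 0.858, adjusted p = 0.858 over 5 relations, r = 0.34 without the 2 farthest libraries, rho = 0.33, exact permutation p = 0.428, adjusted p = 0.535). It was 0.60 in intrahepatic cholestasis (permutation p = 0.0568, adjusted p = 0.142, r = 0.71 without the 2 farthest libraries, rho = 0.60, permutation p = 0.0744, adjusted p = 0.186). The lower of the 2, 0.08, leaves the hypothesis open, since with 8 libraries neither a relation nor its absence was shown in biliary atresia. In the 14 libraries that did not stand apart, both groups pooled, r was 0.61 (permutation p = 0.0176, adjusted p = 0.088) and 0.28 without the 2 farthest. There rho was 0.58 (permutation p = 0.034, adjusted p = 0.169). Whether the correlations differ between the groups was not tested.

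The form of the sample code, which follows no disease group, went with expression. With the disease group in the model, 476 of 15098 genes differed between the 13 libraries of the most common form and the 5 others. Of these, 321 were higher and 155 lower in the most common form (limma), and 0 were among the 36 genes that differed between the diseases. A share of 476 in 15098 would leave few or none of 36 genes shared by chance. The 0 therefore does not show that the 36 are free of the code form. The correlation across genes of a library's fold with transcript length, in which genes are not independent replicates, was 0.251, 0.262, 0.279 and 0.378 in 4 of the 5 other libraries and -0.0426 in the fifth. It was at most 0.0629 in the 13 of the most common form. Within that form the cholangiocyte, chemokine and regulatory T cell differences were 1.54, 1.26 and 0.58, and in the 5 others, 3 with biliary atresia and 2 with intrahepatic cholestasis, 0.26, 0.95 and 0.17. Whether the differences depend on the form was not tested.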
